A study of Mus musculus with 6 samples.

How the data were processed

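Libraries were made from rRNA-depleted total RNA with a stranded kit, per the labels' protocols. Per the submitters' processing notes, FastQC, TopHat 1.0.0 and Cufflinks were used with build mm10; their roles, the read counter and its use of strand are not given in the sources used here. Antisense and overlapping genes, and near-identical copies, are therefore uncertain. The deposited table has the column names of a DESeq2 results table, per the file headers. The signal in its group columns is the authors' mean over libraries of read counts divided by a size factor per library. Deposited log2 fold changes and their standard errors are the authors' and are positive where the heterozygote mean is higher; they are drawn towards 0, as for genes with few reads or a wide spread between libraries. The deposited score of each gene is its log2 fold change divided by the standard error. The deposited p-values are two-sided, with an adjusted p missing for 10989 genes, which mostly lie under a mean of 8.76 normalized counts; these stayed missing.

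Genes were counted once by identifier (26778 identifiers, 26677 of them matched in the reference annotation). Symbols that a spreadsheet had turned into dates, 23 in number, were replaced through their identifiers. A gene was called at a deposited adjusted p of 0.05 with a mean of at least 1 normalized count. Log2 ratios are of the group means with a pseudocount of 1, which understates the change of low genes. The design foresaw per-sample values or group values; the table holds group values, so the authors' test was counted, as fixed before the data were examined.

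For 32 gene lists fixed before the data were examined, the calls were counted over all genes and after Benjamini-Hochberg adjustment over the list alone. Each list median was placed among 10000 random lists of the same size matched on deciles of mean expression, with Benjamini-Hochberg adjustment over the lists. This placement was planned as a description only. Random lists draw genes independently, so their p-values leave out the spread between libraries and the correlation within a list. Named genes followed a fixed rule: Flt1, S100a8 and S100a9, up to 4 members of each list with the smallest adjusted p, the 10 highest and 10 lowest called log2 ratios among named genes, and the 5 most abundant called genes. Csf3r, Ly6g, Cxcr2, Elane, Mpo, Prtn3, Ctsg, mt-Co2, Gm20716, H2-Ea-ps, H2-Eb1, Ifi202b and Nnt were named after their values were seen. Some genes that the rule takes are not reported here.

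Counts per library were an addition made after the table was seen. A group mean is a sum of 3 whole numbers, each times a step of 1/(3 × size factor), and the steps and whole counts were solved from the low and moderate means. A unique solution in both groups was found for 26174 genes (97.7%); the others have means too high to resolve. Size factors recomputed as median ratios from the recovered counts lay within 0.157% of those solved. On simulated wild type means 26216 of 26779 genes came back right and 0 wrong. The recovered counts were tested with limma 3.58.1 in R 4.3.3 (trend, log2 of normalized count + 1, mean of at least 10, 14964 genes). On simulated counts for these 14964 genes with a dispersion of 0.0139, limma called 86% of genes changed 2-fold and 100% of genes changed 4-fold, with 13 unchanged genes called. The simulation gave every gene this 1 dispersion and drew genes independently. Its rates therefore do not carry over to genes with a wider or shared spread between libraries. camera with a preset correlation of 0.01 and with an estimated correlation, cameraPR and fry were run on the lists, and adjusted p values named with an estimated correlation come from camera. camera and fry used only list members in the limma fit, such as 22 of 36 HIF targets and 7 of 21 macrophage identity genes. Deposited call counts and list medians also cover members without recovered counts. Principal components were taken from the log2 values that limma used, centred and not scaled by gene.

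Python 3, numpy, pandas and scipy were used for the remaining steps. The labels do not say that the libraries of a group came from separate animals. The p-values of tests between libraries therefore measure the spread between these libraries, which may be technical. Intervals cover counting error only. Where genes that every cell uses are listed at 0, as mt-Co2 is, a 0 can be a failed count; such genes are given as listed at 0, without a fold. A single-value exact permutation test of 3 against 3 libraries cannot go below p = 0.1 and was not used.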

Results

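RNA sequencing was carried out on bone marrow-derived macrophages, which are macrophages grown from mouse marrow in medium that supports their differentiation. Cells of day 7 of culture were starved of serum and held at 2% oxygen for 6 h. The 6 libraries came from wild type mice (Flt1+/+, n = 3) and from mice labelled heterozygous for Flt1 (Flt1+/-, n = 3). Flt1 encodes VEGF receptor 1. Both groups received the same challenge, so the comparison asks how the genotypes differ under hypoxia and starvation, and no untreated library was analysed here. The authors' deposited table lists 26778 genes with a mean normalized count per group and a test between the groups. Whole read counts per library were recovered from the group means for 26174 genes, and library values below, given as mean ± SD, are these recovered normalized counts. By the recovered size factors the libraries held between about 25130000 and 42070000 counted reads. Recovered libraries carry the letters A, B and C within a group because the table does not tie them to replicate numbers.

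Flt1 (ENSMUSG00000029648, chromosome 5, 147561604 to 147726011, build mm10) was not lower in the libraries labelled Flt1+/-. It stood at 6.66 ± 3.32 normalized counts (SD, n = 3) in wild type and at 12.7 ± 4.47 (SD, n = 3) in the libraries labelled heterozygous. The authors' deposited table gives a log2 fold change of 0.30 with a standard error of 0.24 and an adjusted p of 0.641. The test therefore did not call the difference, although the means lie further apart than either SD. With so few reads the targeted gene does not check the genotype labels. Every direction below is between libraries as labelled.

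The deposited test called 953 of 15789 tested genes at an adjusted p of 0.05, with 397 higher and 556 lower in the libraries labelled Flt1+/-. Among called genes that the naming rule allows, which leaves out predicted genes such as Gm20716, the 10 highest log2 ratios were those of the neutrophil granule genes Ngp, Ltf, Camp and Retnlg, of S100a8 and S100a9, the subunits of calprotectin, and of Syce1, Chil3, Pla2g4d and Padi4. By deposited calls, 25 of 36 targets of hypoxia-inducible factors and 13 of 18 immediate early and stress genes were lower, and 13 of 20 sterol synthesis and 11 of 31 cell cycle genes were higher. With an estimated correlation the adjusted p was 0.092 for the first of these lists and 0.23 for each of the others. At the preset correlation of 0.01, camera gave these lists adjusted p of at most 1.13e-11, and fry gave 0.0014 to 0.043. The estimated correlations, 0.043 to 0.57, lie above that preset. The deposited count rests on the authors' test. limma on the recovered counts called 310 of 14964 genes, 115 higher and 195 lower, and between 42 (without wild type library B) and 326 (without heterozygote library B) when 1 library was left out.

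The libraries also fell into sets that cross genotype. The mitochondrial gene mt-Co2 was listed at 0 in wild type library C and heterozygote libraries B and C, and at 4260, 4070 and 4751 normalized counts in wild type A, wild type B and heterozygote A. In a principal component analysis of the recovered libraries, the second component (22.8% of variance) separated these sets, at 10.5 to 40.7 for the libraries with mt-Co2 reads and -31.3 to -21.8 for the others. The first (33.4%) was -40.5 to -26.3 in wild type libraries. In Flt1+/- libraries it was 53.2 in A, 39.0 in C and only 1.55 in B. On the same log2 values, heterozygote library B had its highest correlation with wild type library B, at 0.967. It was 0.9643 with heterozygote C, 0.9637 with wild type C, 0.9605 with wild type A and 0.9577 with heterozygote A. limma called 4 genes between the sets. The defining gene, mt-Co2, was kept in the principal components and in this fit, so neither is independent of it. With the set as a term, limma called 448 genes between genotypes, of which 279 were also called without it. Each set holds at most 2 libraries of a genotype, so within-set values below carry no test.

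S100a8 and S100a9, which encode calcium-binding proteins abundant in neutrophils and monocytes, rose in the libraries labelled Flt1+/-. Cell makeup was not measured, so a rise within macrophages cannot be told apart from a difference in the cells present. S100a9 stood at 91.4 ± 12.7 normalized counts in wild type and 1507 ± 94.985 in Flt1+/- (SD, n = 3 each), and the authors' deposited table gives a log2 fold change of 3.67 with a standard error of 0.15 and an adjusted p of 6.55e-131. S100a8 stood at 47.1 ± 2.27 and 774 ± 89.0, with 3.51, 0.17 and 1.10e-90 in the authors' deposited table. Of 10 tested genes on the S100 list, 3 rose and 0 fell, both over all genes and adjusted over the list alone. The third was Ager, a receptor for S100 proteins, with a log2 fold change of 0.78 in the authors' deposited table; limma called 2 of 10 with all libraries and in each omission of 1 library, which with all libraries were S100a8 and S100a9 and not Ager (adjusted p 0.108). The adjusted p of this list was 0.23 with an estimated correlation.

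Of 12 tested markers of neutrophils and their precursors, 8 rose and 1 fell, over all genes and adjusted over the list alone. Ngp, a neutrophil granule protein, went from 11.5 ± 1.47 to 708 ± 157 normalized counts and Ltf, lactoferrin, from 8.90 ± 1.44 to 349 ± 131 (SD, n = 3 each). Retnlg and Camp, with log2 fold changes of 1.67 and 1.60 in the authors' deposited table, also rose. Csf3r, the receptor for granulocyte colony-stimulating factor, was the member that fell, from 7890 ± 199 to 5436 ± 359. The primary granule genes Elane, Mpo, Prtn3 and Ctsg had mean values of at most 4.96 normalized counts in either group. The list median was 1.72 on the log2 scale, above all 10000 random lists matched on mean expression, and the adjusted p was 0.093 with an estimated correlation. Within the library sets the recovered members had medians of 1.81 and 1.28. limma called 5 of 12 higher and 1 lower, and 2 higher and 0 lower without wild type library B, wild type library C or heterozygote library C.

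**Figure D1:**
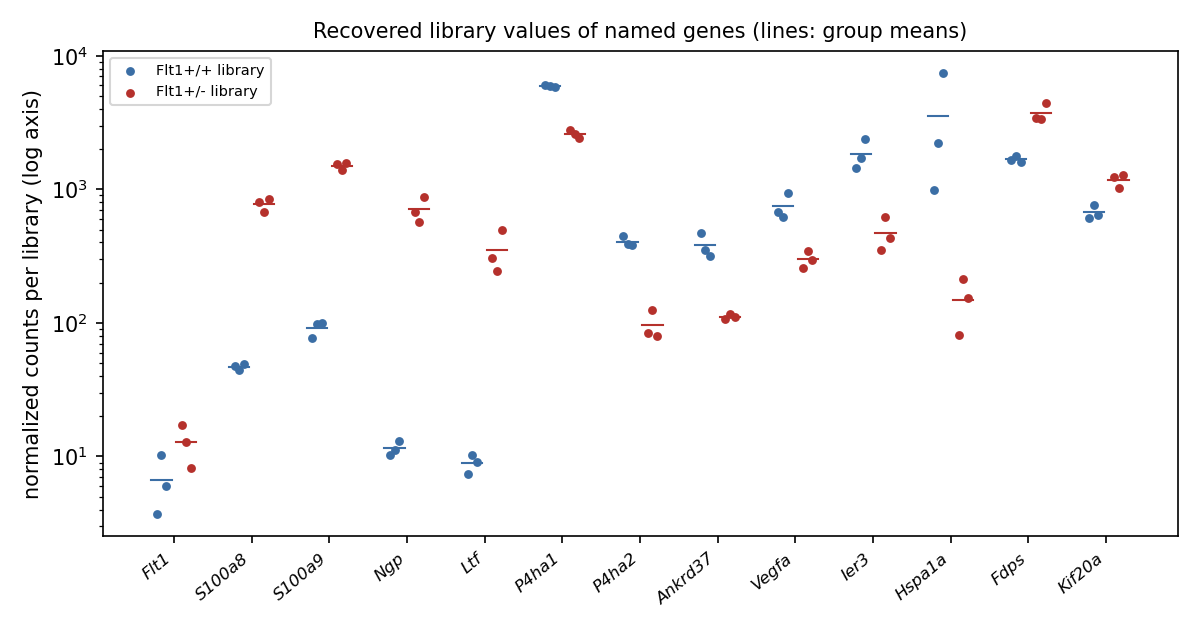
Normalized counts of 13 named genes in each recovered library on a log axis, with a line at each group mean; blue points are Flt1+/+ and red points are Flt1+/- libraries (3 each). S100a9 lay near 91.4 in wild type and 1507 in Flt1+/- libraries, while the Flt1 values of the groups overlapped.

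Hypoxia-inducible factors (HIF) are transcription factors stabilised by low oxygen. Of 36 tested HIF targets, 25 fell and 0 rose, and 28 fell when adjusted over the list alone. P4ha1, a subunit of collagen prolyl 4-hydroxylase, went from 5934 ± 84.1 to 2599 ± 167 normalized counts (SD, n = 3 each), and the authors' deposited table gives an adjusted p of 2.19e-27. P4ha2 went from 406 ± 33.4 to 95.8 ± 24.8 and Ankrd37 from 382 ± 81.5 to 112 ± 5.31. Ldha, lactate dehydrogenase A, had a log2 fold change of -0.89 in the authors' deposited table. Vegfa, a ligand of the Flt1 receptor, fell from 748 ± 168 to 301 ± 44.7, and Vegfb also fell; no other of the 10 tested VEGF receptors and ligands was called, and Kdr had an adjusted p of 0.561 in the authors' deposited table. limma called Vegfa but not Vegfb (adjusted p 0.067), and of 6 members of the VEGF list it called 0 in every omission of 1 library except that of heterozygote library B, where it called 2. The HIF list median was -0.80, below all 10000 matched random lists, with an adjusted p of 0.092 with an estimated correlation. Within the library sets it was -0.88 and -0.90 over the 22 members with recovered counts. limma called 12 of these 22 lower, 3 without wild type library A, wild type library C or heterozygote library C, and 4 without wild type library B.

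Of 18 tested immediate early and stress genes, which are rapidly induced by many stimuli, 13 fell and 0 rose. The count adjusted over the list alone was also 13. Ier3 went from 1855 ± 487 to 469 ± 139 normalized counts, Dusp1, a phosphatase of MAP kinases, from 2272 ± 593 to 726 ± 42.5, and Nr4a3 from 411 ± 242 to 39.9 ± 7.17 (SD, n = 3 each). Hspa1a, a heat shock protein 70 gene, varied widely between wild type libraries, at 3551 ± 3414 against 149 ± 67.1. Hspa1a and Hspa1b are near-identical, so their separate values are uncertain. The list had an adjusted p of 0.23 with an estimated correlation. limma called 7 of 18 lower, 12 with the library set term, 2 without heterozygote library A, 3 without heterozygote library B and 0 without wild type library B, wild type library C or heterozygote library C.

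Of 18 chemokines and NF-kB early targets, 7 fell and 1 rose (8 and 1 adjusted over the list alone). limma called 4 of 17 lower, 7 with the library set term, 1 without wild type library C or heterozygote library A, and 0 without wild type library B or heterozygote library C. Ccl4 fell from 3601 ± 688 to 1193 ± 162 normalized counts and Cxcl2 from 1120 ± 479 to 171 ± 31.8 (SD, n = 3 each). Some markers of each macrophage activation state fell. Of 16 tested pro-inflammatory genes 4 fell and 0 rose (5 and 1 adjusted over the list alone), among them Ptgs2, Tnf and Socs3. Of 17 tested alternative activation genes 7 fell and 1 rose (9 and 2 adjusted over the list alone). Irf4, a transcription factor, fell from 540 ± 32.5 to 185 ± 18.9, Cd163, a scavenger receptor, from 234 ± 16.1 to 70.8 ± 8.47. Mrc1, the mannose receptor, stood at 10183 and 4635 in the group means of the authors' deposited table and also fell. Chil3, which neutrophil precursors also express, was the member that rose. These 3 lists each had an adjusted p of 0.23 with an estimated correlation. limma called 3 of 16 pro-inflammatory genes lower, and 0 without wild type library B or heterozygote library C, 1 without wild type library A, wild type library C or heterozygote library A. Of 15 alternative activation genes limma called 4 lower and 1 higher, with 2 lower when any library but wild type A was left out. Of 14 JAK-STAT3 genes 3 fell and 0 rose, namely Osm, Socs3 and Fos. Socs3 is also counted among the pro-inflammatory genes and Fos among the immediate early and stress genes. The count adjusted over the list alone was the same, and the adjusted p was 0.358 with an estimated correlation. limma called 2 of 13 JAK-STAT3 genes lower, 1 without wild type library A or heterozygote library A, and 0 without wild type library B, wild type library C or heterozygote library C.

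Of 20 sterol synthesis genes tested, 13 rose and 0 fell, with 16 higher adjusted over the list alone. limma called 9 of 20 higher, 4 without heterozygote library A, 1 without wild type library A or heterozygote library C, and 0 without wild type library B or C. Fdps went from 1676 ± 82.2 to 3744 ± 625 normalized counts and Fdft1, squalene synthase, from 679 ± 68.2 to 1563 ± 396 (SD, n = 3 each). Among 19 lipid handling genes 4 rose and 3 fell (4 and 5 adjusted over the list alone), with the desaturase genes Scd1 and Scd2 higher and Plin2, a lipid droplet protein, lower; limma called 1 of 13 lipid handling genes higher and 2 lower, and 0 in either direction without wild type library B, wild type library C or heterozygote library C. Of 31 cell cycle genes 11 rose and 0 fell, with 16 higher adjusted over the list alone; Kif20a, a mitotic kinesin, went from 673 ± 85.3 to 1177 ± 140. limma called only 1 of 31 higher with all libraries, 4 without heterozygote library B and 0 in each of the other omissions. The sterol and cell cycle lists each had an adjusted p of 0.23 with an estimated correlation.

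**Figure D2:**
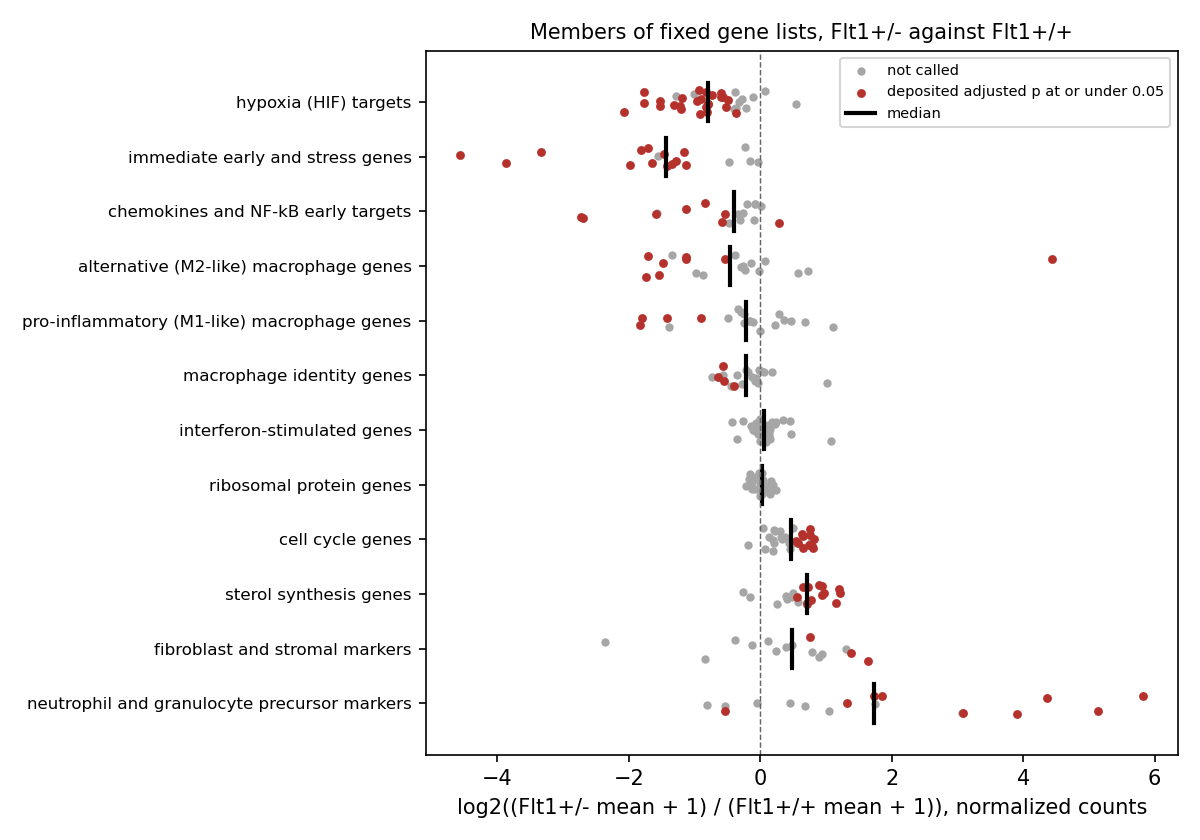
Each point is a gene of a fixed list, placed by the log2 ratio of its group means (pseudocount 1); red points had a deposited adjusted p at or under 0.05 and black lines are list medians. The HIF targets lie mostly left of 0 (median -0.80) and the neutrophil markers mostly right of it (median 1.72).

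The deposited test called 0 of 32 interferon-stimulated genes over all genes and 0 adjusted over the list alone. This list varied widely within each genotype, with an SD of its median between libraries of 0.56. Mx1 ranged from 292 to 771 normalized counts in wild type and from 337 to 1428 in Flt1+/- libraries, so a difference could be missed. Ribosomal protein genes gave 0 of 30 in both counts, and mitochondrially encoded genes 0 of 6. The mitochondrial median, over 3 recovered members, had an SD between libraries of 2.73. MHC class I genes fell in 3 of 14 (4 adjusted over the list alone), namely H2-K1, H2-D1 and B2m, while no MHC class II gene of 9 tested was called over all genes and 1 was adjusted over the list alone. Reads of MHC class I genes can be shared between family members. limma called 1 of 12 MHC class I genes lower, and 0 without heterozygote library C or any 1 wild type library. Macrophage identity genes fell in 4 of 21 (8 adjusted over the list alone), and limma called 0 of the 7 it could test. With an estimated correlation the adjusted p was 0.589 for MHC class I, 0.585 for MHC class II and 0.358 for macrophage identity genes. Csf1r, the receptor for macrophage colony-stimulating factor, had a log2 fold change of -0.54 in the authors' deposited table. Matrix and angiogenic factors gave 1 rise and 4 falls among 20 (1 and 6 adjusted over the list alone), with Hbegf lower at 29.4 ± 9.88 against 143 ± 21.5 and Fn1, fibronectin, higher; limma called 1 of 20, lower, and not Fn1 (adjusted p 0.130), and 0 without heterozygote library C or any 1 wild type library. Amino acid starvation targets gave 1 rise and 2 falls among 23 (2 and 3 adjusted over the list alone), while limma called 0 of 21, and 2 lower with the library set term.

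Markers of other cells moved in different directions. Fibroblast and stromal markers rose in 3 of 12 (4 adjusted over the list alone), with Acta2, smooth muscle actin, at 97.7 ± 17.5 and 255 ± 20.7 normalized counts; limma called 1 of 12, and 0 without wild type library A, wild type library B or heterozygote library C. Dendritic cell markers fell in 2 of 9 in both counts, and limma called 0 of 9. B and plasma cell markers fell in 2 of 4 in both counts, and limma called 1 of 3, and 0 without wild type library B, wild type library C or heterozygote library A; Igkc, the kappa light chain gene, stood at 358 ± 102 and 15.1 ± 14.2. Vwf rose among 7 endothelial markers and Gp1ba among 6 erythroid and megakaryocyte markers, where 2 more fell when adjusted over the list alone. Cd4 was the call among 3 T and NK cell markers and was lower. With all libraries limma called Gp1ba and neither Vwf nor Cd4, and Gp1ba was not called in any omission of 1 library. Of 2 tested mast cell and basophil markers 0 were called over all genes, and 1 rose when adjusted over the list alone. With an estimated correlation the adjusted p was 0.23 for stromal, 0.278 for dendritic, 0.23 for B and plasma cell and 0.819 for erythroid and megakaryocyte markers. Of 9 replication-dependent histone genes, Hist2h4 fell; limma called 1 of 8 lower, and 0 in every omission of 1 library except that of heterozygote library B.

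Within 10 Mb of Flt1, 13 of 173 tested genes were called, or 7.51% with an exact Clopper-Pearson 95% interval of 4.06 to 12.5, against 6.02% elsewhere (Fisher's exact test, two-sided p = 0.419). Among 19 tested neighbours of Flt1, Slc7a1 was higher and no other was called, in both counts. Of 4 tested sex-linked genes Eif2s3y rose, from 977 ± 75.5 to 2426 ± 294 normalized counts, while Ddx3y stood at 2949 ± 45.9 and 2986 ± 508. No other sex-linked gene was called. limma called 1 of these 4 higher and 0 lower, with all libraries and in each omission of 1 library. Of 25 tested genes known to differ between mouse strains, Ly6c2 rose and no other was called over all genes; 2 rose when adjusted over the list alone. limma called neither Slc7a1 nor Ly6c2. The most abundant called genes were Fth1, Psap, Itm2b and Ctsb, which were lower, and Actg1, which was higher.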

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

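The limma fits on recovered counts, the library set term, cameraPR, camera and fry were chosen after the data were seen. Against the 953 called genes (397 higher, 556 lower), an adjusted p of 0.01 gave 575 (222 higher, 353 lower), a change of at least 2-fold 320 (122, 198) and Bonferroni adjustment 260 (84, 176). limma gave 310 (115, 195), with quantile normalization 296 (121, 175), with a pseudocount of 0.1 307 (114, 193) and with the library set term 448 (151, 297). Leaving out 1 library in limma gave 42 to 326 genes (17 to 122 higher, 23 to 204 lower); the count was 100 without wild type A, 42 without wild type B, 46 without wild type C, 129 without heterozygote A, 326 without heterozygote B and 63 without heterozygote C. Fewer samples enter each of these fits; the cause of the other differences was not tested. Other filters and recomputed Benjamini-Hochberg values stayed within 1.5 times. Flt1 was higher in the libraries labelled Flt1+/- under every alternative run, from 0.30 to 1.203 on the log2 scale, and passed none; leaving out 1 library gave 0.57 to 1.203. Against matched random lists, which leave out the spread between libraries, 16 of 31 lists tested passed. With cameraPR on the deposited scores 17 lists passed. Of 30 lists tested on recovered counts, 17 passed with camera at the preset correlation of 0.01 and 10 with fry. With camera and an estimated correlation 0 passed, so the number passing depends on the correlation assumed. List medians kept within the spread between libraries in 146 of 155 alternatives and moved in 8. Of lists that passed against matched random lists, 1 turned sign: the erythroid and megakaryocyte median, -0.50, reversed to 0.072 with a mean of at least 5, where fewer genes enter. Lists that did not pass also turned sign, as with the mean in place of the median, where B and plasma cell markers went from 0.076 to -0.68 and neighbours of Flt1 from 0.026 to -0.067. No paired analysis was possible because the table's columns carry no replicate numbers. Depth limits Flt1 and the primary granule genes, which had few reads per library.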

Other observations

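The list of actin cytoskeleton and SRF targets and that of endoplasmic reticulum chaperones were chosen after some of their members had been seen. Of 24 tested actin genes 10 rose and 0 fell; without the members seen first 3 of 17 rose, with p = 2.80e-05 by cameraPR and 0.0979 with an estimated correlation. Of 20 tested chaperones 7 fell and 0 rose; without the members seen first 2 of 15 fell, with p = 0.00775 by cameraPR and 0.147 with an estimated correlation.

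Of the tests that follow, those on neutrophils, library scaling, the medians without 1 library, plates and H2-Ea were chosen after the result was seen. The real split of the 6 recovered libraries gave 310 genes in limma and the highest of the other splits 4; with 1 of 10 splits as large, the design cannot give a share under 0.05.

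By deposited calls 8 of 12 neutrophil markers, the granule genes Ngp, Ltf and Camp among them, were higher in the libraries labelled Flt1+/-, with an adjusted p of 0.093 with an estimated correlation. Promyelocytes as the only source are argued against, since Elane, Mpo, Prtn3 and Ctsg summed to 0.946% ± 0.266 (SD, n = 3) of Ngp there. A mixture of promyelocytes with later stages was not tested. Later neutrophil stages in these cultures may be a source, but this stays open. Of 16 markers under 50 normalized counts in wild type 8 rose, Ly6g and Cxcr2 included, and 8 were not called. Among the uncalled, 7 had no deposited adjusted p and so could not be called, Elane, Mpo, Prtn3 and Ctsg included. The number not called therefore says little about later stages. An action of the genotype within macrophages cannot be told apart from this, because cell makeup was not measured. The same limit holds for S100a8 and S100a9, which rose in the same libraries. Csf3r, which macrophage cultures also express, changed by -0.52 in the authors' deposited table.

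By deposited calls, HIF targets and immediate early and stress genes were lower in the libraries labelled Flt1+/-, with adjusted p of 0.092 and 0.23 with an estimated correlation. A factor common to all genes of a library is argued against: the HIF median less that of ribosomal protein genes, which such a factor cannot change, was -0.83, with an SD of the HIF median between libraries of 0.095, and that of immediate early and stress genes was -1.46. For a single deviating library, the test fixed beforehand came out in its favour, as limma called 12 HIF targets with all libraries and 3 at the lowest without 1, but this fell below the bound in 4 of 6 omissions. The medians, examined afterwards, argue against 1 library as the only source of the lower values. They were -0.84 to -0.96 for HIF targets and -1.21 to -1.67 for immediate early and stress genes. A library that only widens the difference is not excluded by them. limma calls of immediate early and stress genes went from 7 to 0 in 3 omissions, and Hspa1a stood at 988, 2239 and 7427 in wild type. A difference in oxygen, starvation or handling between plates cannot be told apart from genotype, as no label separates them; immediate early genes had a median of -1.44.

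Excluding genes with means too high to recover, 6 genes were listed at 0 in every library of 1 genotype and had at least 10 normalized counts in each of the other: Ttll6, Ighg1, Igha and Igkv4-53 (listed at 0 in Flt1+/-), and Syce1 and Gm20716 (listed at 0 in wild type). Whether an overlapping gene took their reads cannot be told apart: 1 of 6, Gm20716, overlaps any gene of the table, so the outcome fixed beforehand for this cause could not occur; the genes it overlaps, Adnp (4037 in wild type and 3128 in Flt1+/-) and Dpm1 (906 and 851), were not called. The labels name C57BL/6 mice, whose H2-Ea carries a promoter deletion; that every animal carried this form is argued against, as H2-Ea-ps had 75.7% to 107% of the reads of its neighbour H2-Eb1 in every library. A background difference between the genotypes may remain, but the number of such genes cannot decide it. Another split, which follows the library sets through mt-Co2 and pseudogenes, also held 6 such genes, and the remaining splits held 0 to 3. The deposited test called all of the real 6, at adjusted p from 0.00070 (Igkv4-53) to 6.55e-39 (Ttll6), and 3 of these are antibody genes.

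Other genes known to differ between mouse strains were read beside the labelled C57BL/6 strain. Ifi202b stood at 1311 ± 414 and 1167 ± 380 normalized counts and Nnt at 3071 ± 230 and 3028 ± 229 in wild type and Flt1+/- libraries (SD, n = 3 each).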
